A study of Mus musculus with 23 samples.

How the data were processed

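RNA was measured in 23 bulk sequencing libraries made from sections of mouse tumours grown under the skin from TC2Ras cells, a prostate adenocarcinoma line. The labels describe stranded poly(A) libraries, paired-end sequencing and an RNA integrity number of at least 8. Per the submitters' processing notes, cutadapt, HISAT2, StringTie and DESeq2 were used with genome build GRCm38. Their versions and settings are not given in the sources used here, nor is the step that turned alignments into gene values.

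The authors deposited 1 table of estimated counts per gene, with 55401 Ensembl gene identifiers and 23 columns. The deposited values are whole numbers, so rounding them changed nothing. They are not plain fragment counts, because 143 genes hold the same nonzero value in all 23 libraries. Of counts from 1 to 40, 31.7 to 35.3% per library are multiples of 4, where an even spread gives 1 in 4. Gene symbols and GRCm38 coordinates came from the GENCODE annotation, with 55034 identifiers given a symbol and 367 left without one. The 107 identifiers that share a symbol with a larger entry are shown by identifier. It is not stated whether the counting used strand, so values of overlapping antisense genes are uncertain. The same holds for genes with close copies, which here include Hba-a1 and Hba-a2, Hspa1a and Hspa1b, the tubulins, the granzymes and the H2 genes.

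Samples were grouped by title into 12 groups, which cross an empty vector (EV) or an IL-27 vector (IL27v) given in vivo with 6 ex vivo conditions. Each group has 2 libraries except IL27v with ex vivo IL-27, which has 1, numbered replicate 2. The descriptions of the 3 ex vivo IL-27 samples repeat a single library name, so their titles were used. Nothing says that replicates came from separate animals or whether pieces of 1 tumour were shared between ex vivo conditions, so p-values measure only the spread between these samples, which may be technical. Libraries are named by vector, ex vivo condition and replicate number.

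Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the filterByExpr filter by group and the quasi-likelihood test (glmQLFit and glmQLFTest) on 24440 genes. All 23 libraries entered 1 cell-means model of the 12 groups, with 11 residual and a median of 5.75 prior degrees of freedom and a biological coefficient of variation of 0.62. The vector effect is the mean of the 6 within-condition differences. Each exposure is compared with media as the mean of the differences under the 2 vectors, and a vector interaction is the difference between those 2. Exposures share their media libraries, so their fold changes are not independent of each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived as the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled counts relative to library total (CPM), given as mean ± SD over libraries.

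A collection of 34 lists of pathway and cell-type genes, with 466 distinct members, was fixed before the data were examined, as were the tests, the naming rule and a first group of alternatives. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. In 9 comparisons this called 110 lists. With an estimated correlation none of the 110 calls held. Fry, which asks whether a list's genes move on balance in one direction, called 14 lists, of which 13 are among the 110. Genes could be named from the 10 largest increases and the 10 largest decreases among called genes that qualified, and not all of these are named. To qualify, a gene needed a mean of at least 1 CPM, an assigned symbol and the same sign across vectors, or across at least 5 of the 6 conditions. Up to 4 members per list with the smallest p could also be named. The genes Il27, Ebi3, Il27ra, Cd3e, Cd4, Cd8a, Gzmb, Ifng, Cd274, Cxcl9, Socs3, Mki67, Met, Kdr and Hras are named as well. The results of 1 further gene and of 1 list are not reported here, though both stayed in the tests. The sign rule was not applied to the vector effect in media or to interactions. Where 20 or fewer genes were called, all with a symbol could be named.

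That first group was DESeq2 1.42.0, DESeq2-type size factors (RLE), no filter, a filter of 1 CPM in 4 libraries, a replicate block, an additive model, a fold threshold, fits on fewer libraries, the other list tests and leaving out each library in turn. Added after seeing the data were counts divided by 4, removal of each library's trend with GC content by an offset (a smoother of span 0.3, with GC values for 99.8% of tested genes), leaving out 3 libraries with the most rRNA or the steepest GC trends, and fits that account for skeletal muscle transcripts or for 3 sets of libraries. The sets were told apart by 2 signals in the data. Set B has at least 5 CPM of Ngp, set C has at least 100 CPM over 13 muscle genes without Ngp, and set A has neither. The 13 are the muscle list without Eno3, which is also expressed in libraries without the other members. Sums of the muscle list include Eno3. IL27v docetaxel 1, which has neither as well, was put in no set because it has the highest rRNA share.

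The pipeline was tested on simulated counts for the same 24440 genes. For the vector effect it recovered 31.3%, 53.7% and 63.6% of genes changed 2-, 4- and 8-fold, with 8 false calls among 118. For docetaxel it recovered 4.5%, 31.3% and 45.5%, with 1 false call among 58, and for the cabozantinib plus IL-27 by vector interaction 0%, 3% and 15.2%, with 0 false calls among 12. Apart from the changes put in, the simulated libraries shared 1 mean per gene. These runs held no sets of libraries, muscle signal or GC trends, so their false calls say nothing about such structure in the real libraries. With library totals and TMM factors, 1 CPM stands for 36.3 to 86.5 counts.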

Results

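Male C57BL/6 mice, 8 to 10 weeks old, carried flank tumours of TC2Ras cells, which are TRAMP-C2 mouse prostate adenocarcinoma cells carrying an activated Ras. Each mouse received 10 µg of plasmid per muscle in the tibialis anterior of the leg by sonoporation, in which ultrasound and microbubbles open cells to DNA. The plasmid was empty (EV, called cold) or encoded IL-27 joined to a short peptide (IL27v, called hot). IL-27 is a cytokine made of an Il27 and an Ebi3 chain, a secreted signal between immune cells. Tumour pieces were then held ex vivo in media or with cabozantinib (an inhibitor of MET, VEGF receptor and other kinases), docetaxel (a microtubule-stabilising taxane), an antibody to PD-L1, IL-27, or cabozantinib plus IL-27. The stated purpose of the sequencing was to look for stronger T-cell components in hot than in cold tumours. With library totals and TMM factors, 1 CPM (TMM-scaled) stood for 36.3 to 86.5 counts. The 11 replicate pairs correlated at 0.933 to 0.968 across genes, against 0.887 to 0.974 over all pairs of libraries. The closest pair was thus not a replicate pair.

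The libraries fell into sets that the vector and ex vivo labels do not explain. Set A held 9 EV libraries with at most 18.4 CPM summed over 13 skeletal muscle genes and at most 0.118 CPM of Ngp, a neutrophil granule protein. Set B held 5 libraries of both vectors, EV anti-PD-L1 2, both EV cabozantinib plus IL-27 and both IL27v media libraries, with 483 to 711 CPM of muscle transcripts and 14.1 to 18.8 CPM of Ngp. In set C, 8 IL27v libraries had 618 to 974 CPM of muscle transcripts and 0 CPM of Ngp. Junb, a subunit of the AP-1 transcription factor, lay at 3.17 to 64.1 CPM in set A, 0.267 to 1.13 in set B and 47.6 to 182 in set C. The slope of log2 levels on GC content ran from -3.32 to 10.4 in set A, -12 to -2.8 in set B and 0.88 to 6.79 in set C. IL27v docetaxel 1 belonged to no set, with 27.2% of its counts from 1 ribosomal RNA gene and 28.7 CPM of muscle transcripts. In no ex vivo condition were both vectors in the same set. This rests on leaving out IL27v docetaxel 1, which by muscle and Ngp levels alone would share set A with the EV docetaxel libraries. The sets follow the order in which the samples are listed. Set B is 1 unbroken run, set C is another apart from IL27v docetaxel 1, and set A holds the first and last places. The list is also ordered for the most part by vector and condition, and whether it reflects handling is not known. The labels name no batch, and whether samples were exchanged or pieces of 1 tumour shared between conditions is not known.

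**Figure D1:**
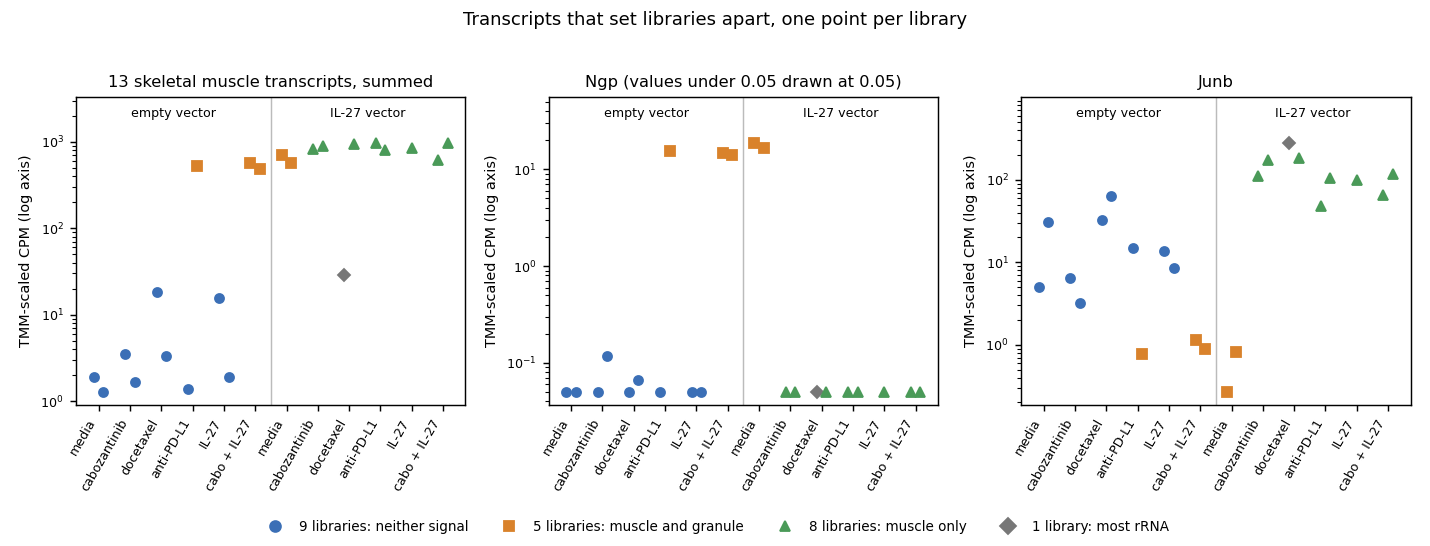
Summed level of 13 skeletal muscle transcripts, Ngp and Junb in each of the 23 libraries, in TMM-scaled CPM on log axes, by vector and ex vivo condition, with colour and shape for the set of libraries. The 5 set B libraries have 14.1 to 18.8 CPM of Ngp and 0.267 to 1.13 CPM of Junb.

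Averaged over the ex vivo conditions, inflammatory chemokines and MHC class I genes were higher in IL27v than in EV tumours. Cxcl1 and Cxcl5, chemokines that attract neutrophils, rose by 1.97 ± 0.33 (log2 fold change ± SE) and 4.59 ± 0.82 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0046 and 0.0056). They were above the median of all 12 EV libraries in 9 and 11 of 11 IL27v libraries. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347 in GRCm38), a class I heavy chain, went from 90.4 ± 33.6 CPM (n = 12) to 210 ± 101 CPM (n = 11; edgeR adjusted p = 0.017). Nlrc5 (ENSMUSG00000074151, chromosome 8, 94434356 to 94527272), the transactivator of class I genes, rose by 1.90 ± 0.38 (edgeR adjusted p = 0.012). Ddit3, a transcription factor of the integrated stress response, fell by 1.11 ± 0.21 on the log2 scale. Flt3, a cytokine receptor of blood progenitors and dendritic cells, fell by 1.05 ± 0.16 (edgeR adjusted p = 0.0088 for Ddit3 and 0.0021 for Flt3). Each was below the median of all EV libraries in 11 of 11 IL27v libraries. The dendritic cell list, which holds Flt3, leaned the other way and was not called. Of its 12 members 1 rose and 1 fell (median 0.72; camera adjusted p = 0.52, adjusted p = 0.8 with an estimated correlation). Granzymes D, F and G, serine proteases of cytotoxic granules, were lower. Gzmd was at 8.05 ± 5.29 CPM in EV and 1.58 ± 1.9 CPM in IL27v (edgeR adjusted p = 0.0054). Gzmf was at 6.67 ± 4.96 and 0.542 ± 0.581, and Gzmg at 7.98 ± 5.63 and 0.627 ± 0.74 (edgeR adjusted p = 0.0081 for both).

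Of the fixed lists, the NF-kB and inflammatory cytokine list had 7 of 20 members that rose, 17 when adjusted over the list alone, and a median log2 difference of 1.27 (camera adjusted p = 4.3e-08, adjusted p = 0.47 with an estimated correlation). In the MHC class I presentation list 4 of 13 rose, 6 when adjusted over the list alone (median 0.98; camera adjusted p = 0.0013, adjusted p = 0.56 with an estimated correlation). That median was 0.47 without IL27v media 2 and 0.54 without IL27v cabozantinib 2. Immediate early genes, which answer stimulation within minutes, had 6 of 12 members that rose, 7 adjusted over the list alone (median 0.71; camera adjusted p = 2.9e-05, adjusted p = 0.3 with an estimated correlation). Among them were Junb (2.51 ± 0.41) and Jun (1.01 ± 0.18; edgeR adjusted p = 0.0035 and 0.0053). Of mitochondrially encoded transcripts 2 of 9 rose, 3 adjusted over the list alone (median 0.22; camera adjusted p = 0.0052, adjusted p = 0.56 with an estimated correlation). The 2 are mt-Nd5 and mt-Nd1, which encode subunits of respiratory complex I (1.14 ± 0.20 and 0.87 ± 0.17; edgeR adjusted p = 0.0052 and 0.01). Aen, a p53-induced nuclease, rose by 0.88 ± 0.15 (edgeR adjusted p = 0.0054). The heat shock protein genes Hspa1a and Hspa1b rose by 2.60 ± 0.32 and 1.99 ± 0.23 (edgeR adjusted p = 0.0012 for both). With the sets of libraries as a term the signs of Junb, Jun, Hspa1a and Hspa1b turned, with none called (-1.66 ± 1.12, -0.17 ± 0.49, -1.46 ± 0.97 and -0.39 ± 0.69).

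Camera called further lists between the vectors. Upward these were MHC class II, p53 and type I interferon genes (camera adjusted p = 0.0099, 0.0027 and 0.041, adjusted p = 0.56, 0.3 and 0.8 with an estimated correlation). Downward they were fibroblast, unfolded protein response and hypoxia genes (camera adjusted p = 0.0031, 0.007 and 0.041, adjusted p = 0.56 for each with an estimated correlation). Leaving out EV cabozantinib 2 or EV IL-27 2 lost MHC class II (adjusted p up to 0.068), and leaving out IL27v media 1 lost the fibroblast list (adjusted p = 0.056). The hypoxia call was lost without EV cabozantinib 2, EV anti-PD-L1 1, EV cabozantinib plus IL-27 2, EV IL-27 2, IL27v media 2, IL27v docetaxel 1, IL27v anti-PD-L1 2 or IL27v cabozantinib plus IL-27 1 (adjusted p up to 0.13). The type I interferon call was lost without any 1 of 12 libraries (adjusted p up to 0.64). These are EV media 2, cabozantinib 2, docetaxel 1, anti-PD-L1 1, cabozantinib plus IL-27 1 and IL-27 2, and IL27v media 2, cabozantinib 2, docetaxel 2, anti-PD-L1 2, cabozantinib plus IL-27 1 and IL-27 2.

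Transcripts of other tissues moved with the vector. Of 14 skeletal muscle genes 13 rose, also when adjusted over the list alone (camera adjusted p = 3.6e-20, adjusted p = 0.21 with an estimated correlation). The muscle list summed to 192 ± 239 CPM in EV (n = 12) and 812 ± 290 CPM in IL27v (n = 11). Acta1 (skeletal actin) was up by 5.43 ± 0.74 and Tnnt3 (fast troponin T) by 5.41 ± 0.72 (edgeR adjusted p = 0.0016 and 0.0013). Of 6 erythroid genes 4 rose, 5 adjusted over the list alone (camera adjusted p = 0.00034, adjusted p = 0.43 with an estimated correlation). The globin genes Hba-a1 and Hba-a2 were up by 3.32 ± 0.44 and 3.22 ± 0.45 (edgeR adjusted p = 0.0013 and 0.0016). Of 11 keratinocyte genes 4 rose, also when adjusted over the list alone (camera adjusted p = 1e-05, adjusted p = 0.3 with an estimated correlation). Their sum was 5.07 CPM in EV and 337 ± 654 CPM in IL27v, where 3 libraries held 373 to 1780 CPM. Krt6a, a keratin of activated skin, lay at 0.195 ± 0.394 and 196 ± 386 CPM (edgeR adjusted p = 0.0034), a call lost without IL27v media 1 (adjusted p = 1). With the sets as a term Krt6a had -1.95 ± 3.40.

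In total 722 genes were called between vectors by edgeR, 558 higher and 164 lower in IL27v, with 3538 at an unadjusted p under 0.05 and 2104 called by DESeq2 (1324 higher and 780 lower). With IL27v docetaxel 1 placed in no set, vector and set of libraries cannot be told apart within any condition. An additive model called 666 genes. With the sets as a further term, resting on the 3 EV and 2 IL27v libraries of set B, it called 0 (edgeR, 677 at an unadjusted p under 0.05). In set B the vectors share no ex vivo condition, so that fit takes the exposure effects from the other sets. Its 0 does not show that the vector had no effect. With presence of the muscle signal as the further term, the additive model called 2. The count was 1244 without EV IL-27 2, and 457, 481, 471, 394, 462, 447 and 434 without EV media 1, EV media 2, EV cabozantinib 2, EV cabozantinib plus IL-27 1 and 2, IL27v cabozantinib 2 and IL27v cabozantinib plus IL-27 1 in turn.

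T-cell transcripts, the subject of the stated question, were low in both kinds of tumour. Cd3e, a chain of the T-cell receptor complex, was at 0.188 ± 0.237 CPM in EV (n = 12) and 0.284 ± 0.218 CPM in IL27v (n = 11), and no library exceeded 0.645 CPM. The coreceptors Cd4 and Cd8a were at 0.43 ± 0.425 and 0.142 ± 0.293 CPM in EV and at 0.853 ± 0.709 and 0.155 ± 0.247 CPM in IL27v. Gzmb, the main granzyme of killer cells, was at 4.79 ± 5.81 and 9.91 ± 15 CPM, and Ifng at 0.0588 and 0.0942 CPM. The 18 T-cell genes summed to 10.6 ± 4.5 CPM in EV and 13.2 ± 6.61 CPM in IL27v, with 9.23 ± 2.49 CPM over the 9 libraries of set A, 13.2 ± 6.51 over the 5 of set B and 13.5 ± 7.25 over the 8 of set C. By edgeR 0 of the 18 passed over all genes, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.62 with an estimated correlation). The camera call was lost in 8 of 23 fits that each left out 1 library (EV cabozantinib 2, EV anti-PD-L1 1, EV IL-27 2, IL27v media 2, IL27v cabozantinib 2, IL27v docetaxel 2, IL27v anti-PD-L1 2 or IL27v cabozantinib plus IL-27 1; adjusted p up to 0.23). The CD4 and regulatory T-cell list was called as well (camera adjusted p = 0.033, adjusted p = 0.56 with an estimated correlation), with 0 of 7 members past edgeR, and was lost in 8 such fits (EV cabozantinib 2, EV docetaxel 2, EV anti-PD-L1 1, EV IL-27 2, and replicate 2 of IL27v media, cabozantinib, docetaxel and anti-PD-L1; adjusted p up to 0.12). With a filter of 1 CPM in 4 libraries camera's direction for the T-cell list was down, though not called (adjusted p = 0.83).

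Transcripts of the introduced cytokine and its receptor were also compared. The plasmid was given in leg muscle and the RNA came from flank tumours, so these levels do not measure its expression in the muscle. Between the vectors edgeR called none of Il27, Ebi3, Il27ra, Socs3, Mki67 and Kdr. Il27 was at 0.0354 ± 0.0518 CPM in EV and 0.0634 ± 0.0997 in IL27v, and Ebi3 at 0.227 ± 0.257 and 0.341 ± 0.266. Il27ra, the receptor chain, was at 3.39 ± 1.26 and 2.82 ± 0.889 CPM. Of genes that cytokines induce, the chemokine Cxcl9 was at 3.13 ± 4.83 and 7.22 ± 13.3, the PD-L1 gene Cd274 at 21.2 ± 15.4 and 32.8 ± 22.8, and the feedback inhibitor Socs3 at 48.6 ± 20.5 and 70.5 ± 31.2. The proliferation marker Mki67 was at 217 ± 66.2 and 178 ± 65.2 CPM, Hras at 25.8 and 24, the cabozantinib target Met at 49.5 and 49.1, and the VEGF receptor gene Kdr at 7.44 ± 3.42 and 11.5 ± 5.95 CPM.

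**Figure D2:**
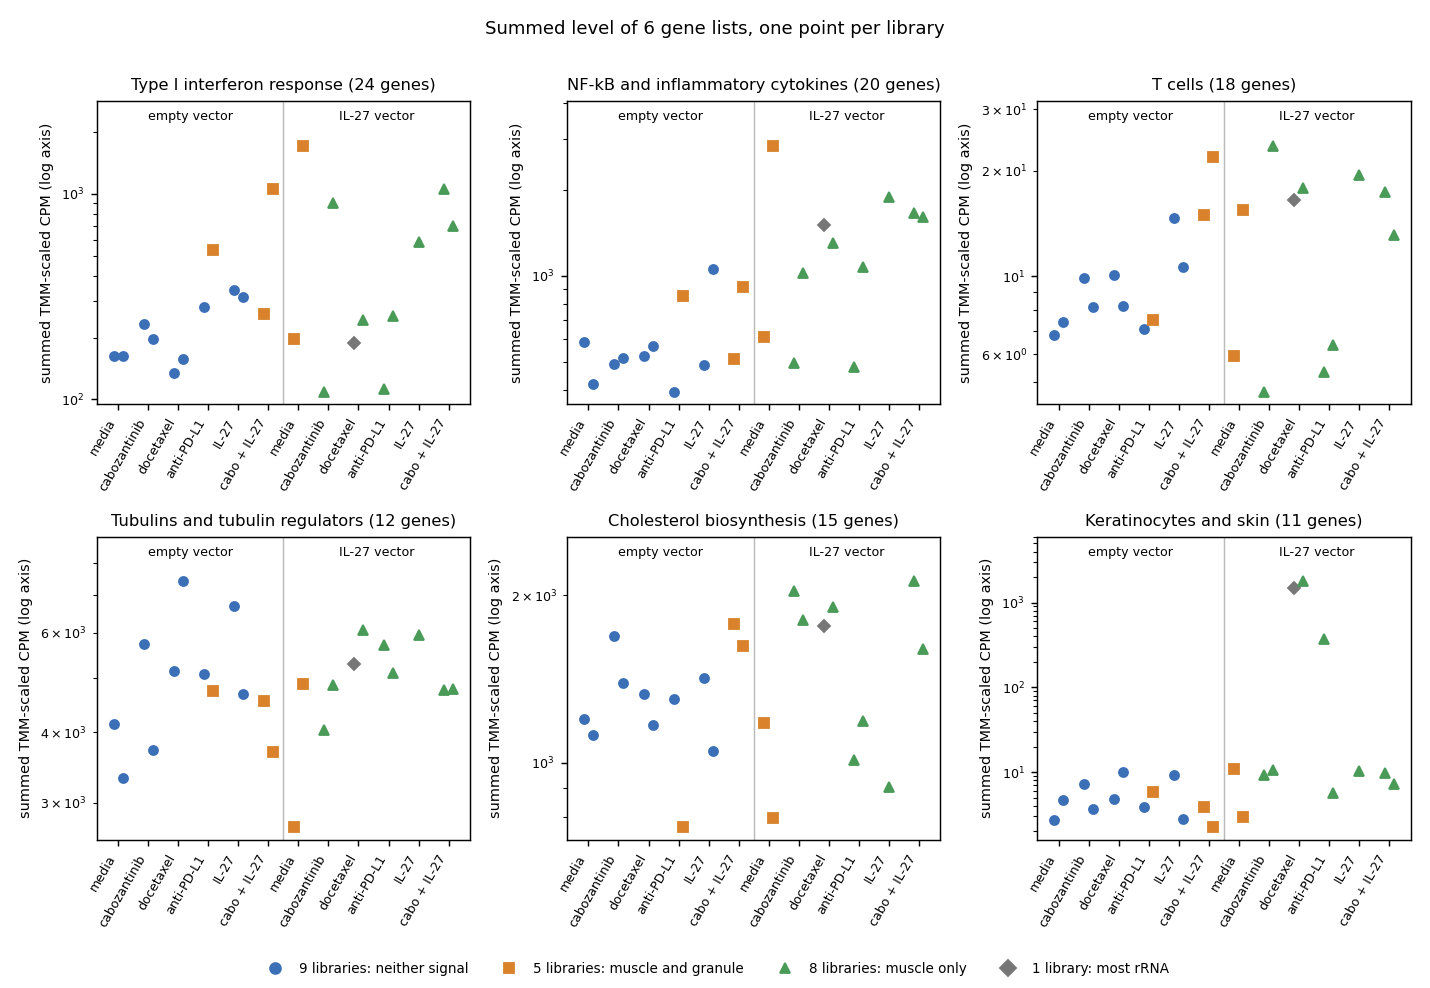
Summed level of 6 gene lists in each of the 23 libraries, in TMM-scaled CPM on log axes, by vector and ex vivo condition, with colour and shape for the set of libraries. IL27v media 1 and 2 lie at 196 and 1720 CPM of type I interferon genes, and the 2 IL27v docetaxel libraries at 1500 and 1780 CPM of keratinocyte genes.

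With no drug ex vivo, interferon-response genes separated 1 IL27v library from the other media libraries. The 24 type I interferon genes summed to 1720 CPM in IL27v media 2, against 196 in IL27v media 1 and 163 in both EV libraries. Cytotoxic lymphocyte genes summed to 101 CPM in IL27v media 2 and 5.48 CPM in IL27v media 1. Gbp4, an interferon-induced GTPase, had a log2 difference of 5.22 ± 1.34, and Oas3, which senses double-stranded RNA, one of 3.56 ± 1.10 (edgeR adjusted p = 0.19 and 0.24). Adjusted over the list alone, 20 of 24 type I interferon genes rose (median 3.07; camera adjusted p = 6.1e-07, adjusted p = 0.54 with an estimated correlation). Markers of other cells moved too. The endothelial list had negative medians, from -3.17 to -0.44 over single libraries left out. It summed to 595 and 218 CPM in IL27v media 1 and 2 and to 518 and 458 CPM in EV media 1 and 2. Adjusted over the list alone, 7 of 12 neutrophil, 13 of 14 muscle and 4 of 9 mitochondrially encoded transcripts rose (camera adjusted p = 2.4e-10, 2.7e-13 and 3.2e-07, adjusted p = 0.26, 0.49 and 0.49 with an estimated correlation). The mitochondrial transcripts summed to 34800 and 41900 CPM against 20900 and 21000 CPM. T-cell genes were called (camera adjusted p = 0.0015, adjusted p = 0.54 with an estimated correlation), but not without IL27v media 2 (adjusted p = 0.54). Immediate early genes, higher in IL27v on average over the conditions, were lower in media (median -0.83, 3 of 12 fell adjusted over the list alone; camera adjusted p = 0.00051, adjusted p = 0.49 with an estimated correlation). By edgeR 0 genes were called between the vectors in media, with 2209 at an unadjusted p under 0.05 and 855 called by DESeq2. Without IL27v media 2 the count was 303 and the interferon call was lost (median 0.35, adjusted p = 0.73), and without IL27v media 1 it was 13. The IL27v media libraries belong to set B and the EV ones to set A, and their muscle lists summed to 759 and 639 against 50.6 and 36.5 CPM.

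Docetaxel went with higher tubulin transcripts under both vectors. Tubb6 (ENSMUSG00000001473, chromosome 18, 67390717 to 67402749), a beta-tubulin, was at 247 ± 2.35 CPM in EV media and 625 ± 210 in EV docetaxel, and at 124 ± 88.4 and 603 ± 10.8 CPM under IL27v (n = 2 each). The log2 rise was 1.81 ± 0.32 (edgeR adjusted p = 0.012), seen in 4 of 4 docetaxel libraries. Tubb2b and Tubb2a rose by 2.06 ± 0.37 and 1.83 ± 0.35 (edgeR adjusted p = 0.013 and 0.018). Of 12 tubulin genes and regulators 4 rose, 8 adjusted over the list alone (median 0.90; camera adjusted p = 1.3e-07, adjusted p = 0.63 with an estimated correlation). Within set A, which holds the EV docetaxel and media libraries, all 12 had positive differences, with a median of 0.98 (camera adjusted p = 1.7e-08, adjusted p = 0.81 with an estimated correlation). There Tubb6, Tubb2b and Tubb2a had 1.34 ± 0.44, 1.72 ± 0.52 and 1.54 ± 0.48 (edgeR adjusted p = 0.96 for each). The tubulin list was also called upward for ex vivo IL-27, the antibody to PD-L1 and the combination, with smaller medians (0.69, 0.42 and 0.32; camera adjusted p = 3.5e-06, 7.3e-06 and 0.0059, adjusted p = 0.62, 0.77 and 0.61 with an estimated correlation). For the combination that call was lost without EV media 2, EV cabozantinib plus IL-27 1 or IL27v media 1 (adjusted p up to 0.5, medians from 0.08 to 0.21), and the median was 0.63 without IL27v media 2. Other lists moved within set A with docetaxel: 13 of 13 measured muscle genes, 7 of 8 adipocyte genes and 13 of 18 T-cell genes had positive differences (camera adjusted p = 4.8e-05, 0.015 and 0.014, adjusted p = 0.81 for each with an estimated correlation). Averaged over vectors the muscle list was not called (camera adjusted p = 0.89). Adipocyte and T-cell genes were (camera adjusted p = 0.021 and 0.046, adjusted p = 0.83 for both with an estimated correlation). The adipocyte call was lost without EV media 2, EV docetaxel 1, IL27v media 2 or IL27v docetaxel 1 (adjusted p up to 0.13). The T-cell call was lost without EV media 1, EV docetaxel 1, IL27v media 1 or IL27v docetaxel 2 (adjusted p up to 0.3).

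Immediate early genes were also higher with docetaxel. Of 12, 6 rose, 11 adjusted over the list alone (median 1.15; camera adjusted p = 1.8e-09, adjusted p = 0.14 with an estimated correlation). Within set A the median was 0.68 (camera adjusted p = 0.00019, adjusted p = 0.81 with an estimated correlation). Ier2 and Junb rose by 3.84 ± 0.58 and 5.09 ± 0.78 (edgeR adjusted p = 0.0068 for both), against 1.77 ± 0.68 and 1.45 ± 0.77 within set A (edgeR adjusted p = 0.96). Phlda1, an output of RAS-MAPK signalling, rose by 2.11 ± 0.32 (edgeR adjusted p = 0.0068; 1.43 ± 0.54 within set A). Of keratinocyte genes 2 of 11 rose, 4 adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.44 with an estimated correlation; within set A camera adjusted p = 0.49). Sfn, an epithelial 14-3-3 protein, was at 1.07 ± 0.144 and 3.95 ± 2.5 CPM in EV media and docetaxel and at 1.03 ± 0.741 and 239 ± 38.5 CPM under IL27v. Of endothelial genes 3 of 17 rose, 7 adjusted over the list alone (median 1.06; camera adjusted p = 4.8e-05, adjusted p = 0.63 with an estimated correlation). Within set A the median was -0.05 (camera adjusted p = 0.95), and the pooled call was lost without IL27v media 2 (median 0.68, adjusted p = 0.13), while the median was 2.07 without IL27v media 1. Gdf15, a stress-induced cytokine and p53 target, was at 0 CPM in all 4 media libraries, 0.499 ± 0.0729 in EV docetaxel and 2.45 ± 2.27 in IL27v docetaxel.

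In total edgeR called 437 genes for docetaxel, 430 higher and 7 lower, and DESeq2 1795 (1458 higher and 337 lower). The higher genes had a median GC content of 58.3%, against 49% over all tested genes, and removing each library's GC trend left 114. The count was 0 without EV media 1, so no docetaxel gene call held there. It was 44, 68, 61, 1251 and 52 without EV media 2, EV docetaxel 2, IL27v media 1, IL27v media 2 and IL27v docetaxel 1. Under IL27v the comparison crosses from set B to set C and to the library in no set. Within set A edgeR called 1 gene (Rab43, a small GTPase, -8.35 ± 0.68, adjusted p = 0.0038, named after its value was seen), with 356 at an unadjusted p under 0.05.

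With cabozantinib, cholesterol synthesis genes had mostly positive differences. Adjusted over the list alone, 9 of 15 rose, with a median of 0.64 (camera adjusted p = 7.5e-07, adjusted p = 0.93 with an estimated correlation). Within set A the median was 0.43 (camera adjusted p = 0.057, adjusted p = 0.47 with an estimated correlation). Fdps, a farnesyl diphosphate synthase, had 1.21 ± 0.41 in the pooled fit and 1.12 ± 0.73 within set A (edgeR adjusted p = 0.38 and 1), and was above media in 4 of 4 libraries. Within set A, where EV cabozantinib and media libraries are compared, all 16 macrophage and monocyte genes had positive differences, with a median of 1 (camera adjusted p = 1.9e-07, adjusted p = 0.47 with an estimated correlation). Averaged over vectors the list was not called (median 0.49; camera adjusted p = 0.15). It was called without IL27v media 2 or IL27v cabozantinib 1 (adjusted p = 0.028 and 2e-04) and turned without IL27v cabozantinib 2 (adjusted p = 0.94). That list summed to 752 and 468 CPM with cabozantinib against 356 and 334 CPM in media. T-cell, cytotoxic lymphocyte and dendritic cell genes were also called upward within set A (medians 1.21, 1.15 and 1.7; camera adjusted p = 0.0055, 0.0063 and 0.00087, adjusted p = 0.47, 0.47 and 0.29 with an estimated correlation). The T-cell list summed there to 9.89 and 8.2 CPM with cabozantinib and to 6.79 and 7.39 CPM in media, with 0 of 18 genes up adjusted over the list alone. Endothelial genes, whose VEGF receptor the drug inhibits, had a pooled median of 0.90, and 5 of 17 rose adjusted over the list alone (camera adjusted p = 0.00092, adjusted p = 0.98 with an estimated correlation). Within set A the median was 0.14, with 10 of 17 positive differences (camera adjusted p = 0.79), and the pooled call was lost without IL27v media 2 (adjusted p = 0.68). The pooled median was 1.54 without IL27v media 1 and 0.25 without IL27v cabozantinib 2. Mitochondrially encoded transcripts were lower (median -0.41; camera adjusted p = 0.0062, adjusted p = 0.98 with an estimated correlation). That call was lost without EV cabozantinib 1 (median -0.20, adjusted p = 0.1), and the median was -0.72 without EV cabozantinib 2. With GC trends removed, camera's direction for mitochondrially encoded transcripts turned and they were not called. By edgeR 0 genes were called for cabozantinib, with 2570 at an unadjusted p under 0.05 and 321 called by DESeq2, and within set A 0 (254 at an unadjusted p under 0.05). Without IL27v media 2 the count was 346, and without EV cabozantinib 2 it was 3.

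With ex vivo IL-27, antigen presentation and interferon genes were higher in EV tumours, all of which lie in set A in this comparison. There, 22 of 24 type I interferon genes had positive differences, with a median of 1.39, and 3 rose adjusted over the list alone (camera adjusted p = 1.4e-11, adjusted p = 0.11 with an estimated correlation). The list summed to 339 and 315 CPM against 163 CPM in both media libraries. Adjusted over the list alone, 9 of 16 macrophage and monocyte genes rose (median 1.58; camera adjusted p = 1.4e-11, adjusted p = 0.19 with an estimated correlation), from sums of 356 and 334 to 891 and 896 CPM. MHC class II genes, which present peptides to helper T cells, had a median of 2.28, with 2 of 8 up adjusted over the list alone (camera adjusted p = 0.00019, adjusted p = 0.4 with an estimated correlation). The T-cell list summed to 14.7 and 10.6 CPM with IL-27 and to 6.79 and 7.39 CPM in media (camera adjusted p = 1.5e-08, adjusted p = 0.17 with an estimated correlation). Other lists moved in the same comparison. All 13 measured muscle genes, all 8 adipocyte genes and 6 of 8 neutrophil genes had positive differences (camera adjusted p = 0.0014, 0.00016 and 0.001, adjusted p = 0.55, 0.4 and 0.4 with an estimated correlation). The muscle list with Eno3 summed to 146 CPM in EV IL-27 1 and 29.3 CPM in EV IL-27 2. Over the 13 muscle genes without Eno3 the sums were 15.6 and 1.9 CPM. EV IL-27 1 also has a steep GC trend (slope 10.4). With GC trends removed the type I interferon list was still called within set A (camera adjusted p = 2.1e-14).

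Averaged over vectors, the IL-27 medians were 0.27 for type I interferon genes (camera adjusted p = 0.11, adjusted p = 0.82 with an estimated correlation), which were not called, and 0.74 for macrophages and monocytes (camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation). The MHC class II median was 1.57 (camera adjusted p = 0.015, adjusted p = 0.73 with an estimated correlation). The T-cell list was called with camera adjusted p = 9e-06 (adjusted p = 0.62 with an estimated correlation). The type I interferon direction turned without IL27v media 1 (adjusted p = 0.42), and without IL27v media 2 the list was called upward (median 1.69, adjusted p = 0.00016). The macrophage and monocyte call was lost without EV IL-27 2 or IL27v media 1 (adjusted p up to 0.19), with medians of 0.46 without IL27v media 1 and 1.49 without IL27v media 2. The MHC class II call was lost without EV IL-27 1 (median 0.57) or IL27v media 1 (adjusted p up to 0.071). Of 6 erythroid genes 4 rose adjusted over the list alone (camera adjusted p = 0.0072, adjusted p = 0.62 with an estimated correlation), a call lost without EV IL-27 1 (adjusted p = 0.087), and IL27v IL-27 2 had 1580 CPM of them. Muscle and neutrophil genes were not called on average over vectors (camera adjusted p = 0.18 and 0.26). Adipocyte genes were (camera adjusted p = 0.017, adjusted p = 0.73 with an estimated correlation), a call lost without EV media 2, EV IL-27 1 or IL27v media 2 (adjusted p up to 0.13). Of 12 tubulin genes and regulators 4 rose adjusted over the list alone (median 0.69; camera adjusted p = 3.5e-06, adjusted p = 0.62 with an estimated correlation), and within set A all 12 had positive differences (median 0.64; camera adjusted p = 7.2e-05, adjusted p = 0.5 with an estimated correlation). Of immediate early genes 10 of 12 rose adjusted over the list alone (median 1.12; camera adjusted p = 1.4e-07, adjusted p = 0.26 with an estimated correlation). Within set A the median was 0.36 (camera adjusted p = 0.11). By edgeR 0 genes were called for IL-27, with 2907 at an unadjusted p under 0.05 and 641 called by DESeq2, and within set A 0 (686 at an unadjusted p under 0.05). Without EV IL-27 2 the count was 3821, and without IL27v media 2 it was 880.

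With the antibody to PD-L1, matrix genes of fibroblasts were lower. Adjusted over the list alone, 6 of 15 fell, with a median of -0.77 (camera adjusted p = 7.3e-06, adjusted p = 0.77 with an estimated correlation), and Fap, a protease of activated fibroblasts, had -2.05 ± 0.47 (edgeR adjusted p = 0.56). Within set A, which leaves 1 antibody library, the fibroblast median was -0.14, and the pooled call was lost without IL27v media 2 (median -0.25, adjusted p = 0.22). Tubulin genes had a median of 0.42, with 1 of 12 up adjusted over the list alone (camera adjusted p = 7.3e-06, adjusted p = 0.77 with an estimated correlation), and 0.50 in the 1 antibody library within set A. The pooled tubulin median was 0.73 without IL27v media 2. Over single libraries left out, medians ran from 0.2 to 0.38 for DNA replication and S phase genes. For immediate early genes they ran from 0.28 to 0.68. In the 1 antibody library within set A these 2 medians were 0.04 and -0.06. Of 14 muscle genes 12 rose adjusted over the list alone (camera adjusted p = 0.00065, adjusted p = 0.89 with an estimated correlation), a call lost without EV anti-PD-L1 2 of set B (adjusted p = 1), and within set A 3 of 13 had positive differences. Of 11 keratinocyte genes 2 rose adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.84 with an estimated correlation). That call was lost without EV media 1, EV anti-PD-L1 2, IL27v media 2 or IL27v anti-PD-L1 1 (adjusted p up to 0.57). By edgeR 0 genes were called, with 1429 at an unadjusted p under 0.05 and 113 called by DESeq2. Without IL27v media 2 the count was 101, and without IL27v anti-PD-L1 2 it was 1.

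The combination was set against each of its parts. Against IL-27 alone, adjusted over the list alone, 8 of 15 cholesterol synthesis genes rose (median 0.80; camera adjusted p = 5.3e-12, adjusted p = 0.18 with an estimated correlation). Within set C, in IL27v tumours, 1 library has IL-27 alone, and all 15 lay higher with the combination than in that library (median 1.19). Cyp51 (ENSMUSG00000001467, chromosome 5, 4081145 to 4104746), a sterol demethylase, had 1.30 ± 0.27 pooled (edgeR adjusted p = 0.63) and 1.51 within set C. Insig1, a sterol-sensing regulator, had 1.49 ± 0.32 (edgeR adjusted p = 0.76) and 1.40. Immediate early genes had a median of -0.61 (camera adjusted p = 3.7e-07, adjusted p = 0.18 with an estimated correlation) and -0.38 within set C. Other lists moved in the pooled fit, which under EV goes from set A to set B. Over single libraries left out, medians ran from 2.61 to 4.23 for muscle and from -1.17 to -0.73 for macrophage and monocyte genes. Within set C they were -0.09 and -0.32.

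Against cabozantinib alone, type I interferon genes were higher, with a median of 1.24 (camera adjusted p = 1.5e-13, adjusted p = 0.52 with an estimated correlation). It was 0.45 without EV cabozantinib plus IL-27 2, 0.78 without IL27v cabozantinib 1 and 2.75 without IL27v cabozantinib 2. Within set C the median was 0.80, and 23 of 24 had positive differences (camera adjusted p = 1.5e-09, adjusted p = 0.83 with an estimated correlation). There the list summed to 1060 and 701 CPM with the combination and to 109 and 908 CPM with cabozantinib. The macrophage and monocyte list was lower in the pooled fit, where 4 of 16 fell adjusted over the list alone (median -0.54; camera adjusted p = 0.0021, adjusted p = 0.52 with an estimated correlation). It did not pass the threshold within set C (median -0.87; camera adjusted p = 0.36), and the pooled call was lost without EV cabozantinib 1, EV cabozantinib plus IL-27 1 or IL27v cabozantinib 2 (adjusted p up to 0.6). Its median was -0.24 without IL27v cabozantinib 2, -0.86 without IL27v cabozantinib 1 and -1.11 without EV cabozantinib plus IL-27 2. Other lists rose in the pooled fit, which under EV goes from set A to set B. Of 14 muscle genes 11 rose adjusted over the list alone, and neutrophil, adipocyte and T-cell genes were called (camera adjusted p = 9.3e-13, 0.0021, 0.028 and 8.5e-06, adjusted p = 0.52 for each with an estimated correlation). Within set C muscle genes were called lower, with 1 of 14 positive (median -0.14; camera adjusted p = 0.036, adjusted p = 0.83 with an estimated correlation). Neutrophil and adipocyte genes were not called there (camera adjusted p = 0.76 and 0.75), while T-cell genes were, upward (median 0.02; camera adjusted p = 0.029, adjusted p = 0.83 with an estimated correlation). The neutrophil call was lost without EV cabozantinib 2 or IL27v cabozantinib 1 (adjusted p up to 0.2), and the T-cell call without IL27v cabozantinib 1 (adjusted p = 0.24). The adipocyte call was lost without either EV cabozantinib library, EV cabozantinib plus IL-27 2, IL27v cabozantinib 1 or IL27v cabozantinib plus IL-27 1 (adjusted p up to 0.77).

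Against media, the combination had a type I interferon median of 1.06 (camera adjusted p = 4.4e-07, adjusted p = 0.45 with an estimated correlation) and a cholesterol synthesis median of 0.74, with 10 of 15 up adjusted over the list alone (camera adjusted p = 1.5e-12, adjusted p = 0.2 with an estimated correlation). The type I interferon median was 0.30 without EV cabozantinib plus IL-27 2, 0.59 without IL27v media 1 and 2.50 without IL27v media 2. T-cell genes were called (camera adjusted p = 5.9e-08, adjusted p = 0.36 with an estimated correlation). Adjusted over the list alone, 13 of 14 muscle, 2 of 9 adipocyte and 2 of 6 erythroid genes rose (camera adjusted p = 7.1e-13, 0.0014 and 0.017, adjusted p = 0.36, 0.4 and 0.45 with an estimated correlation). The adipocyte and erythroid calls were lost without IL27v media 2 or IL27v cabozantinib plus IL-27 1, and the erythroid call also without EV cabozantinib plus IL-27 1 (adjusted p up to 0.11 and 0.076). Mitochondrially encoded transcripts were lower (median -0.43; camera adjusted p = 1.5e-05, adjusted p = 0.39 with an estimated correlation), with medians of -0.71 and -0.22 without EV cabozantinib plus IL-27 1 and 2. Under EV this comparison goes from set A to set B and under IL27v from set B to set C, so no value within a set exists. Vopp1 (ENSMUSG00000037788, chromosome 6, 57727807 to 57825159), a vesicular membrane protein, was the 1 gene called by edgeR against media, against cabozantinib and against IL-27, with -2.64 ± 0.26, -2.13 ± 0.26 and -2.13 ± 0.28 (adjusted p = 0.00045, 0.0068 and 0.016). It was at 2.12 ± 0.581 CPM in EV cabozantinib plus IL-27 and at 46.5 ± 2.3, 58.3 ± 5.85 and 32.9 ± 0.403 CPM in EV media, IL27v media and IL27v cabozantinib plus IL-27 (n = 2 each). Within set C it differed by -0.24 ± 0.21 from cabozantinib (edgeR adjusted p = 1) and by -0.18 from the 1 IL-27 library. DESeq2 called 69, 30 and 84 genes, and 1092, 819 and 1212 had an unadjusted p under 0.05 in edgeR. Against media the count was 14 without IL27v media 2. Against cabozantinib it was 3 without EV cabozantinib 2 and 0 without EV cabozantinib plus IL-27 2 or either IL27v cabozantinib plus IL-27 library. Against IL-27 it was 2 without EV IL-27 2 and 0 without any 1 of the 4 combination libraries.

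Whether a response to an exposure differed between hot and cold tumours was tested as an interaction. For cabozantinib plus IL-27, Junb had a log2 interaction of 11.52 ± 1.61 (edgeR adjusted p = 0.0081). It was at 17.7 ± 18 CPM in EV media, 1.01 ± 0.177 in EV with the combination, 0.544 ± 0.392 in IL27v media and 91.9 ± 36.4 in IL27v with the combination. Mif, a macrophage-activating cytokine, had 7.48 ± 1.40 (edgeR adjusted p = 0.015). Ngp went the other way, at 0 CPM in EV media, 14.4 ± 0.41 in EV with the combination, 17.8 ± 1.5 in IL27v media and 0 in IL27v with the combination (edgeR adjusted p = 0.023). The 4 groups of this interaction lie in sets A, B, B and C. Of 358 genes called by edgeR 350 had positive and 8 negative interactions (1150 by DESeq2), and removing each library's GC trend left 96. The count was 0 without EV media 2 or EV cabozantinib plus IL-27 2. It was 40, 56, 913, 108 and 97 without EV cabozantinib plus IL-27 1, IL27v media 1, IL27v media 2, and IL27v cabozantinib plus IL-27 1 and 2.

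For docetaxel, the interaction called 5 genes by edgeR (273 by DESeq2), all positive. They were Sprr1b and Sprr2g of the cornified envelope, the connexin gene Gjb6, the transcription factor gene Casz1 and the lipid transporter gene Spns2. Sprr1b was at 0.846 ± 0.357 and 1.04 ± 0.733 CPM in EV media and docetaxel and at 0.0743 ± 0.105 and 402 ± 255 CPM under IL27v (edgeR adjusted p = 0.036). For cabozantinib the 5 called genes were Junb, Lmtk3, Prag1, Sf3b4 and ENSMUSG00000118642, which has no symbol (edgeR adjusted p = 0.05 after rounding, 587 genes by DESeq2), and 0 were called with RLE size factors. The docetaxel count was 0 without EV media 1, EV media 2, EV docetaxel 2 or IL27v docetaxel 1, and 2, 15, 61 and 9 without EV docetaxel 1, IL27v media 1, IL27v media 2 and IL27v docetaxel 2. The cabozantinib count was 0 without EV media 2, EV cabozantinib 1, IL27v media 1 or either IL27v cabozantinib library, and 85, 1 and 507 without EV media 1, EV cabozantinib 2 and IL27v media 2. For the antibody to PD-L1 and for IL-27, edgeR called 0 genes, with 1862 and 1012 at an unadjusted p under 0.05 and 488 and 49 called by DESeq2. Their counts were 341 and 19 without IL27v media 2, 173 and 1 for the antibody without EV anti-PD-L1 1 and IL27v anti-PD-L1 2, and 1 for IL-27 without EV IL-27 2.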

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

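The 3 tests of the muscle signal, the test of the sets of libraries and the test of docetaxel alone were chosen after the result was seen. The other tests in this part were set before it. In 35 checks of single libraries within an ex vivo condition 5 stood far from the others, and chance alone picks out about 1 in 20 groups.

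Skeletal muscle transcripts were at 100 CPM or more in 13 of 23 libraries, and IL27v docetaxel 2 had 936 CPM while the next docetaxel library had 28.7. The IL-27 vector does not account for this alone, since 4 libraries lie on the wrong side for their vector. Muscle tissue in the tumour sections was taken to give an SD of the fibre-type ratios of at least 0.5 on the log2 scale. One muscle RNA source spilled into libraries handled together was taken to give less. The larger SD over the 13 libraries was 0.155, on the side of the spill. The limit was set after the values were seen, and both explanations share it. It therefore cannot decide between them. Counting alone would give SDs of 0.057 for Myh4 over Myh1 and 0.068 for Myh2 over Myh4. The SDs seen were larger, at 0.155 and 0.132. No label records handling. Pieces from 1 muscle would give the same ratios, so the source is not settled. An exchange of samples was not tested.

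For cabozantinib plus IL-27, 358 genes differed in response between the vectors by the interaction test. Removing the GC trends of single libraries left 96 genes, and leaving out the library IL27v media 1 left 56, so neither explanation alone accounts for all of them or is excluded. For sets of libraries that cross the comparison, the 350 genes called higher had a median log2 ratio of -1.26 between the 2 EV anti-PD-L1 libraries. These share a treatment but lie in sets B and A, and 98.3% of the genes were lower in the set B library, which this explanation predicts. The 2 libraries also differ in GC slope (-5.05 and -0.16), and the 350 genes had a median GC content of 59.2%, against 49% over all tested genes. The test therefore cannot separate the sets from GC trends. The biological explanation, a different response in hot tumours, was tested only by the interaction itself.

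Keratinocyte transcripts were high in both IL27v docetaxel libraries and in IL27v anti-PD-L1 1, which had 373 CPM while the next library of its condition had 5.88. These 3 libraries follow each other in the sample list. Docetaxel alone does not explain this, as 0 EV docetaxel libraries exceeded 4 times the median of the other EV libraries. Skin in the pieces would raise many skin genes together, and 8 of 11 members were at least 4 times their median in each of the 3 libraries. For 4 of the 8 (Krt1, Flg, Dsg1a and Krtdap) that median is 0, so any nonzero value passes. Krt1 passed at 0.0904 CPM in IL27v anti-PD-L1 1, below the 0.242 CPM of EV anti-PD-L1 2. The test decides nothing for or against skin, and a squamous change in the tumour cannot be told apart from it. The docetaxel interaction with vector, called for 5 genes, rests on the same libraries.

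The share of counts from 1 ribosomal RNA gene was 27.2% in IL27v docetaxel 1 and 1.09% in the next docetaxel library. It was 3.02% in IL27v cabozantinib 1 and 0.531% in the next cabozantinib library. Mitochondrial transcripts made up 5.48% of IL27v docetaxel 1 and 2.94% of the next docetaxel library. The cabozantinib interaction with vector was called for 5 genes.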

How the results depend on the processing

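Every group has at most 2 libraries, and 1 CPM stands for 36.3 to 86.5 counts, so transcripts well under 1 CPM rest on few counts. Where leaving out a library left 1 in a group, that library was taken to vary like the other groups. The cause of a changed count was not tested unless stated. Counts below follow the order vector average, vector in media, cabozantinib, docetaxel, antibody to PD-L1, IL-27, cabozantinib plus IL-27, the 5 interactions in the same order, and the combination against cabozantinib and against IL-27. The fit as reported called 722, 0, 0, 437, 0, 0, 1, 5, 5, 0, 0, 358, 1 and 1 genes.

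RLE size factors moved only the cabozantinib interaction by over 1.5 times, to 0. With no low-count filter the counts were 1631, 1135, 948, 1843, 506, 1093, 353, 829, 531, 1010, 262, 1275, 303 and 216. The 1 CPM filter gave 0 and 2 for the cabozantinib and docetaxel interactions. DESeq2 gave 2104, 855, 321, 1795, 113, 641, 69, 587, 273, 488, 49, 1150, 30 and 84. The additive model gave 0 for docetaxel, the combination and its 2 comparisons with its parts. Without the IL-27 condition the vector count was 1244. With only the libraries of each comparison, counts were 1 in media, 64 for docetaxel, 36 for the combination, 0 for the cabozantinib interaction, and 30 and 0 for the combination against its parts.

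Replicate numbers were tried as a block. They do not pair the samples, since over 55 pairs of groups the correlation of differences ran from -0.34 to 0.30 with 9 over 0.1. With the block the counts were 569 for the vector, 289 for docetaxel, 0 for the cabozantinib and docetaxel interactions, 256 for the combination's interaction and 0 for the combination against IL-27, with 110 list calls, and no other count moved by over 1.5 times.

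The following settings were chosen after seeing the data. Counts divided by 4 gave 0 for the cabozantinib interaction. Removing GC trends gave 114 for docetaxel, 0 for the cabozantinib interaction and 96 for the combination's interaction. Without 3 libraries the counts were 60 in media, 4 for cabozantinib, 56 for docetaxel, 1 for IL-27, 0, 12, 10, 1 and 17 for the interactions, and 2 and 5 for the combination against its parts. The muscle signal as a term in the additive model gave 2 for the vector (37 with GC trends removed), 1 for docetaxel and 0 for the combination and against its parts. The muscle-bearing libraries of 2 conditions, the antibody and the combination, gave 2481 for the vector (871 with GC trends removed). Their EV libraries all lie in set B and their IL27v libraries all in set C. That fit therefore cannot tell the vector from the sets. With the sets as a term in the additive model all counts that could be fitted were 0, including the vector, docetaxel, the combination and its comparisons. The additive model without the sets already gave 0 for all of these but the vector, which had 666. Only the vector count could therefore fall with the sets. Within 1 set docetaxel had 1 and the combination 0 against each part, with or without GC trends.

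Leaving out each library in turn, the counts ran from 394 to 1244, 0 to 303, 0 to 346, 0 to 1251, 0 to 101, 0 to 3821, 1 to 14, 0 to 507, 0 to 61, 0 to 341, 0 to 19, 0 to 913, 0 to 3 and 0 to 2, and the list calls from 88 to 137. Of 110 list calls 0 held with an estimated correlation, and fry called 14 lists, of which 13 are among the 110 with the same direction.

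Among 132 gene results, 127 stayed on the same side of the threshold with RLE and 107 with GC removal. The additive model alone lost 43 calls. With the sets as a further term, which called 0 genes, 24 were not called in either fit, 66 lost their call and 14 changed sign. In the vector average the sign changed for Krt5 (-1.43 ± 3.15), Krt6a (-1.95 ± 3.40), Krt17 (-4.76 ± 3.39), Hspa1a (-1.46 ± 0.97), Hspa1b (-0.39 ± 0.69), Junb (-1.66 ± 1.12), Jun (-0.17 ± 0.49), Ier2 (-1.19 ± 0.95), Perp (0 ± 3.74) and Gab3 (1.48 ± 1.66), with errors that leave the sign open. Lypd3 (-3.65) and Ckmt2 (-0.06) could not be estimated there. In the muscle-bearing libraries Iigp1 had -0.23 and Havcr2 -0.03. For cabozantinib Srebf2 had -0.02 with the sets as a term, -0.22 within set A and -0.24 there with GC trends removed. Within set A with GC trends removed, Srebf2 and Slc2a1 each had -0.09 with docetaxel and Dcn 0.12 with the antibody. For IL-27 Junb had -0.73 with the sets as a term, -0.67 within set A and -1.01 there with GC trends removed.

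The direction of a list is camera's, which ranks it against all other genes, so a list can turn while its median keeps its sign, as endothelial genes did for cabozantinib. Of the list results followed through the alternatives, these turned (camera adjusted p): T cells for the vector with the 1 CPM filter (0.83), neutrophil genes for IL-27 with that filter (0.99), mitochondrial transcripts for cabozantinib (1) and muscle genes for docetaxel (0.9) with GC trends removed, MHC class I for cabozantinib without 3 libraries (0.56) and type I interferon genes for IL-27 without 3 libraries (0.42). Within a set, then with GC trends removed, then with an estimated correlation, they were endothelial genes for cabozantinib (0.79, 0.74 and 0.88), immediate early genes (0.89, 0.7 and 0.96) and muscle genes (0.6, 0.59 and 0.95) for the antibody, and muscle genes for the combination against cabozantinib (0.036, 0.2 and 0.83) and against IL-27 (0.31, 0.29 and 0.85). Type I interferon genes turned upward for cabozantinib (0.00022, 0.00022 and 0.29) and the antibody (3.7e-16, 1.2e-17 and 0.076), and neutrophil genes for IL-27 (0.001, 0.00032 and 0.4). Neutrophil (0.76, 0.68 and 0.93) and adipocyte genes (0.75, 0.68 and 0.93) turned for the combination against cabozantinib. Within a set 1 library holds the antibody in set A and 1 holds IL-27 alone in set C, so p-values there take their spread from other groups. Lists not followed this way turned as well, among them endothelial genes for the antibody (0.046 within set A) and immediate early and cytotoxic genes for cabozantinib (0.003 and 0.0063). Within set A with GC trends removed, endothelial genes with docetaxel (0.59) and erythroid genes with IL-27 (0.64) turned. Over single libraries left out, MHC class I in media ran from 7.1e-11 to 0.7 and type I interferon genes from 0.00016 to 0.42 with IL-27, 1.9e-07 to 0.6 with cabozantinib and 3.7e-08 to 0.86 with the antibody. With cabozantinib macrophage genes ran from 2e-04 to 0.94 and MHC class I from 0.0017 to 0.85, and with docetaxel muscle genes from 0.077 to 0.99.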

Other observations

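Within set A, where EV cabozantinib and EV media libraries are compared, several immune lists were higher with cabozantinib. Of type I interferon genes 23 of 24 had positive differences (median 0.45; camera adjusted p = 0.00022, adjusted p = 0.29 with an estimated correlation), as had all 13 MHC class I genes (median 0.71; camera adjusted p = 0.00049, adjusted p = 0.47 with an estimated correlation). Averaged over vectors neither was called (medians -0.21 and 0.52; camera adjusted p = 0.28 and 0.22). Without IL27v media 1 or IL27v cabozantinib 2 type I interferon genes were called lower (adjusted p = 1.9e-07 and 1.9e-05). Without IL27v media 2 or IL27v cabozantinib 1 MHC class I genes were called higher (adjusted p = 0.0022 and 0.0017). For the antibody to PD-L1 the type I interferon list had a median of -0.52 averaged over vectors (camera adjusted p = 0.33), and was called lower without IL27v media 1 or IL27v anti-PD-L1 2 (adjusted p = 3.7e-08 and 0.021). Within set A, where 1 library holds the antibody, the median was 0.90, which 1 library cannot tie to the antibody.

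Single libraries stood out for other cell types. B-cell genes summed to 234 CPM in IL27v cabozantinib plus IL-27 1 and to at most 19.8 CPM in any other library. Neutrophil genes summed to 245 and 273 CPM in the IL27v docetaxel libraries and to 3.88 and 4.38 CPM in the EV ones. Erythroid genes summed to 1580 CPM in IL27v IL-27 2.

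Other splits of the samples were compared with the actual ones, a test set before the results were seen. For the vector, in an additive model, 60 splits including the actual one were used. As many genes were called in 1 of 60 (666, and at most 2 in any other), and list differences as large appeared in 2 for skeletal muscle (5.58, highest other 5.6), 2 for NF-kB (1.3 and 1.43) and 2 for T cells (1.32 and 1.54). Chance is thus an unlikely explanation for the gene count, if libraries can be interchanged, which tumours shared between conditions would break. For each list 1 other split gave a larger difference, so chance is not excluded there. The splits do not separate vector from set of libraries.

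For each exposure 34 splits were used, in an additive model. There the actual split called 0 genes for every exposure (edgeR). That all 34 called as many is then fixed in advance and decides nothing about the gene calls. The highest of the others was 1 for cabozantinib, 2369 for docetaxel, 0 for the antibody to PD-L1, 3558 for IL-27 and 12 for the combination, or 78 and 6437 for the combination against cabozantinib and against IL-27. The 2369, 3558 and 6437, against 0 for the actual split, point to a structure of the samples. The split with 12 set the 4 set B libraries against the others, and the one with 6437 set C against set B, with 1 EV IL-27 library on each side. Those with 2369 and 3558 divided both set A and set B. Within each vector both put the libraries with the higher GC slopes on 1 side, among them EV docetaxel 2 (6.15) and EV IL-27 1 (10.4). IL27v media 1 (-11.95) lay on the other side in both. Whether these splits follow GC trends was not tested. List differences as large appeared in 2 splits for cholesterol synthesis with cabozantinib, 14 for endothelial genes with cabozantinib, 2 for tubulins with docetaxel, 3 for immediate early genes with docetaxel, 7 for keratinocyte genes with docetaxel and 7 for fibroblast genes with the antibody. They appeared in 6 for immediate early genes with IL-27, 2 for cholesterol synthesis with the combination and 3 for cholesterol synthesis against IL-27. Chance could account for each of these list results.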
